A study of Mus musculus with 4 samples.

How the data were processed

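Total histone H3 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 4 mouse libraries, 1 per group. The groups were untreated V6.5 embryonic stem (ES) cells, V6.5 ES cells kept in 10 uM SB431542 for 24 h, C2C12 myotubes and 38B9 pro-B cells. Per the labels' protocols, whole cell extracts were sonicated to an average of 500 bp and precipitated with an H3 antibody (Abcam AB1791). The DNA then went through 18 cycles of ligation-mediated PCR, and products of 150 to 300 bp were cut from a gel, which corresponds to inserts of 50 to 200 nt. No input library was used here, so a ratio of H3 reads between cell types contains both the DNA copy number and the H3 recovered per copy.

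The deposited files hold 1 signed position per aligned read, with a minus sign for the minus strand, and no count, score or normalisation by the authors. Per the file headers, reads were aligned to mm8 with Bowtie (version not given in the sources used here) with a seed of 36 bases, at most 2 seed mismatches, a summed mismatch quality limit of 70, and only reads with at most 2 places kept. The files have 2 sections, read here as reads with 1 reported place and reads with 2 places, both listed. This reading was inferred from the section names, the alignment options and line counts, since in the second section the remainder after division by 2 was 0 in all 4 files. Per the file headers, 3 libraries came from run 100623 and the SB431542 library from run 100804, so that the treatment and the sequencing run cannot be told apart.

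Repeated reads were kept in the deposited files. Here at most 1 read per position and strand was kept, and reads with 1 reported place were used unless stated otherwise. After this step the libraries held 13494981 (untreated ES), 13852985 (SB431542), 13102915 (myotube) and 13430107 (pro-B) distinct positions. Each library was scaled to its autosomal distinct positions, and the reads of chromosome M to all distinct positions. The smallest position on chromosome 1 was 3000001, and positions were read as counted from 1.

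The 4 comparisons were the SB431542, myotube and pro-B libraries each against untreated ES, and myotube against pro-B. With 1 library per group there was no test between conditions and no replicate check. Ratios are given with exact conditional binomial intervals (95%), which cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Genome bins of 1 Mb with a mean of at least 100 reads over the 4 libraries (2551 of 2639 bins) were called higher or lower by a rule of size, an absolute log2 ratio of 0.5 or more. Runs of 3 or more such neighbouring bins formed regions. Libraries were also compared over autosomal bins of 100 kb with a mean of at least 100 reads, on log2 counts with 0.5 added, by Pearson's r across bins and by the standard deviation (SD) of the log2 ratio. Both were set beside the values that Poisson counting around a shared mean gives, averaged over 20 seeded draws.

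The rule for named features, set before the data were examined, takes the 8 regions with the highest and the 8 with the lowest ratio per comparison where gene coordinates of the right build are not used. The annotation at hand is of GRCm38 and the files use mm8, so that no gene was placed on the reads. The planned promoter profiles, gene list, gene body and CpG results were therefore not analysed here, and neither was the correction for GC content.

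After the data had been seen, several readings were added. Windows of 1 kb were counted as higher in a library when they held at least 20 reads there and at least 3 times the scaled count of the highest other library. Around such pro-B windows, reads were profiled in steps of 250 bp out to 20 kb. For that profile, the windows were chosen on a random part of each library's positions (at least 10 reads) and measured on the remaining positions, with intervals from 1000 resamplings of the windows. Stretches without reads were counted when a library had no read over more than 10 kb and every other library had at least 30. The parts of chromosome 8 described separately were also drawn after its bins had been seen.

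The bin calls were tested on simulated counts for the myotube and untreated ES comparison, with 2551 bins of which 200 were changed. All 36 bins raised 2-fold and all 39 raised 1.5-fold were called, as were all 33 lowered 2-fold and 27 of 28 lowered 1.5-fold. None of the 32 bins raised or the 32 lowered 1.2-fold was called, nor any of 2351 unchanged bins. A 1.2-fold change, a log2 ratio of 0.263, lies below the rule of size. The simulated counts varied by Poisson counting alone, so they do not test the calls under variation between libraries. In the simulated 2628002 windows of 1 kb, 92 of 100 windows raised 6-fold and 61 of 100 raised 4-fold in the pro-B library were called, with 7 calls among the unchanged windows. All 20 stretches emptied in the untreated ES library were found. They had been placed where every library held enough reads for the rule, so this checks the counting procedure only.

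The alternatives chosen at the same time as that rule were all reads as deposited, scaling to the median autosomal 1 Mb bin, no minimum count, a rule of size of 0.3, and thinning to the shallowest library. The alternatives added later were the inclusion of 2-place reads, the SB431542 library as the reference, leaving out chromosome X, leaving out 1 ES library for windows and stretches, and other limits for windows and stretches. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.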

Results

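Chromatin of 3 mouse cell types was precipitated with an antibody against total histone H3, the core histone found in nucleosomes along the whole genome. V6.5 ES cells, of C57BL/6-129 background, were grown without treatment or with SB431542, an inhibitor of TGF-beta type I receptor kinases, at 10 uM for 24 h. C2C12 is a mouse myoblast line, and its cells had been differentiated to myotubes for 48 h in 2% horse serum. 38B9 is a mouse pro-B line, a stage at which the immunoglobulin heavy chain genes are rearranged. Each of the 4 groups had 1 library, with 13888026 reads at 1 place for untreated ES, 14663315 for SB431542, 13568407 for myotubes and 13817365 for pro-B cells. Repeats of the same position and strand made up 2.83%, 5.53%, 3.43% and 2.80% of these reads. No replicate check exists for any difference below, and all intervals are 95% intervals that cover counting error only. The exception is intervals over resampled windows, which cover the spread between windows of the same libraries and treat neighbouring windows as independent.

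The comparison of SB431542-treated with untreated ES cells asks whether H3 occupancy differs after TGF-beta signalling is blocked. The treated library had close to the same H3 distribution as the untreated one. Chromosome 8 stood apart, with 1.08 times the untreated share of reads (interval 1.077 to 1.083, 888220 against 801905 reads). The other 18 autosomes lay between 0.976 and 1.01 times, chromosome X at 1.03 times (1.029 to 1.038) and chromosome Y at 1.01 times (0.974 to 1.042). For 12 of the 19 autosomes the counting interval excluded 1. Of the 128 chromosome 8 bins of 1 Mb, 119 had a log2 ratio above 0. The excess was uneven along the chromosome, at 1.1 times (1.096 to 1.105) from 3000001 to 82000000, 1.07 times from 82000001 to 102000000 and 1.03 times from 107000001 to 131000000. A lower log2 ratio towards the distal end was not particular to chromosome 8, whose difference of -0.107 between bins past 80% and up to 60% of its length lay within the -0.17 to 0.05 of 16 other autosomes, 3 of which were as low.

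No 1 Mb bin reached the rule of size between the ES libraries, and 2550 of 2551 bins had a log2 ratio within 0.25 of 0. The exception was chromosome 7 from 145000001 to 146000000, at a log2 ratio of -0.38 (741 against 941 reads). Across 23365 autosomal bins of 100 kb the libraries correlated with r = 0.944, where counting alone gave 0.969, and no bin differed 2-fold. The log2 ratio spread 1.33 times as wide as counting alone gives. Mitochondrial reads were 1.80 times as frequent in the treated library (interval 1.544 to 2.113), from 463 against 250 distinct positions. The treated library came from another sequencing run than the other 3, and treatment and run cannot be told apart.

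**Figure D1:**
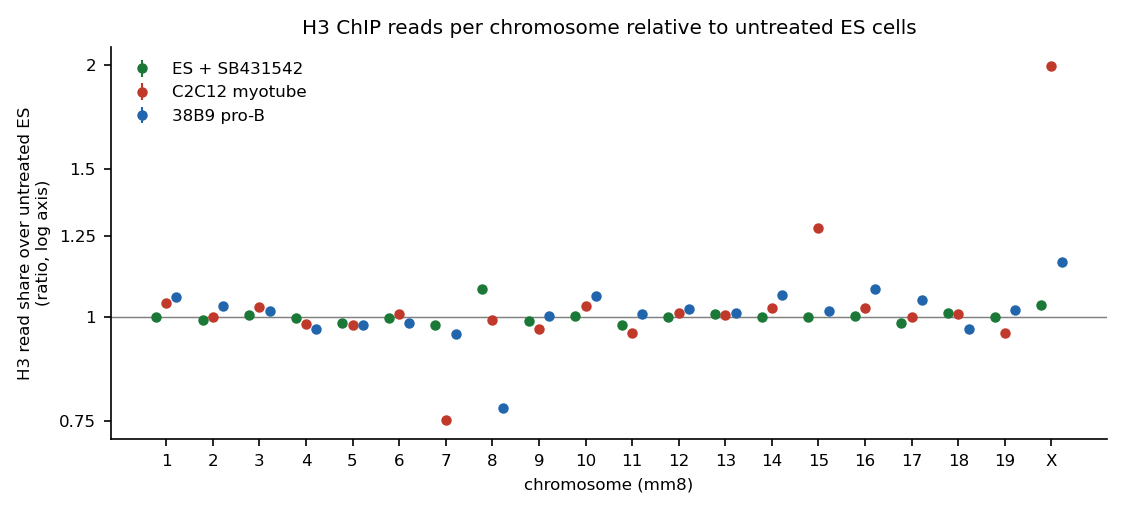
Share of H3 reads on each autosome and chromosome X relative to untreated ES cells, with 1 point per library and chromosome, exact 95% intervals that are mostly smaller than the points, and a log vertical axis. Chromosome X at 1.99 times and chromosomes 7 and 15 at 0.752 and 1.27 times stand out for myotubes, chromosome 8 at 0.778 times for pro-B cells, and chromosome 8 at 1.08 times for SB431542.

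The comparison of myotubes with untreated ES cells asks how the H3 distribution of a differentiated muscle line differs from that of pluripotent cells. Myotubes had 1.99 times the ES share of reads on chromosome X (1.985 to 2.001) and 0.0137 times the share on chromosome Y (0.0109 to 0.0170, 85 against 6557 reads), or 0.0460 times with 2-place reads included. Among autosomes, chromosome 7 was lower at 0.752 times (0.7496 to 0.7552) and chromosome 15 higher at 1.27 times (1.270 to 1.279). The other 17 autosomes lay between 0.956 and 1.04 times. Relative to the median autosome of its own library, chromosome X had a read density of 0.802 in myotubes, 0.405 in untreated ES cells, 0.420 in SB431542-treated ES cells and 0.467 in pro-B cells. Chromosome Y had 0.00616 in myotubes and 0.454 in untreated ES cells. Of the 1 Mb bins, 0 of 139 on chromosome 7 and all 101 on chromosome 15 had a log2 ratio above 0. Such chromosome-wide ratios may reflect DNA copy number in place of H3 per copy. More copies of chromosome X and few or no copies of chromosome Y in myotubes than in ES cells would give both sex chromosome values. Copies were not measured, and without an input library copy number and H3 per copy cannot be told apart.

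Chromosome 8 as a whole was near parity in myotubes at 0.990 times, yet its parts differed. From 82000001 to 102000000 it was 1.65 times the ES level (1.635 to 1.657), and from 107000001 to 131000000 it was 0.676 times (0.671 to 0.682). The proximal part up to 82000000 lay at 0.924 times. The same 3 parts lay at 0.773, 0.796 and 0.777 times in pro-B cells. All bins between 82000001 and 102000000 had a higher level in myotubes, with log2 ratios from 0.46 to 1.01.

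By the rule of size, 186 of the 1 Mb bins were higher and 64 lower in myotubes than in ES cells, and 148 of the higher ones lay on chromosome X. Without chromosome X, 38 bins were higher and 62 lower, and with a rule of size of 0.3 on all chromosomes 251 were higher and 180 lower. They formed 9 regions with higher and 7 with lower reads. The 5 higher regions of chromosome X spanned 147 bins, from 1.94 times (145000001 to 166000000) to 2.06 times (53000001 to 119000000). On chromosome 8 the higher regions ran from 82000001 to 93000000 at 1.67 times and from 94000001 to 102000000 at 1.65 times. On chromosome 15 the higher regions were 66000001 to 72000000 at 1.47 times (1.445 to 1.487) and 46000001 to 49000000 at 1.45 times (1.418 to 1.481). The lower regions lay on chromosomes 7 and 8. On chromosome 8 they were 122000001 to 130000000 at 0.628 times and 109000001 to 116000000 at 0.657 times. On chromosome 7 there were 5, from 0.643 times (41000001 to 46000000) and 0.645 times (23000001 to 31000000) to 0.692 times (96000001 to 101000000). The regions on chromosomes 7, 15 and X lay on chromosomes shifted as a whole, with median log2 ratios over all bins of -0.41, 0.37 and 1.02. Those regions are not read as local features. Across 100 kb bins the myotube and ES libraries correlated with r = 0.759, and the log2 ratio spread 3.06 times as wide as counting alone gives, with 47 bins at least 2-fold apart. The 100 kb bins included chromosomes 7, 8 and 15, whose shifts are part of this spread. In 1 Mb bins the SD of the log2 ratio was 0.217 over all autosomes and 0.422 within chromosome 8. The 100 kb values were not computed without these chromosomes.

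**Figure D2:**
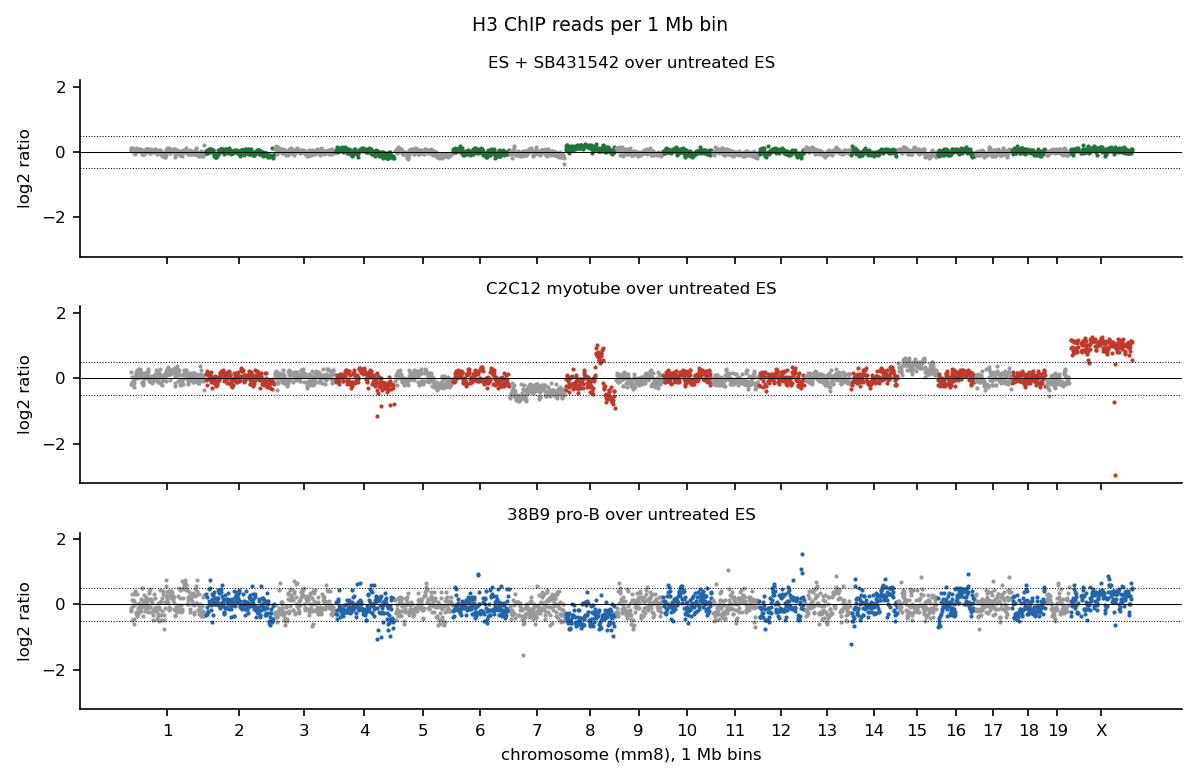
Log2 ratio of H3 reads to untreated ES cells in 2551 bins of 1 Mb, ordered by chromosome in alternating grey and colour, for the SB431542, myotube and pro-B libraries, with dotted lines at the rule of size of 0.5. The SB431542 points stay inside the lines, the myotube points leave them mostly on chromosomes 7, 8, 15 and X, and the pro-B points leave them in 105 bins above and 110 bins below.

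The comparison of pro-B with untreated ES cells asks the same for a lymphoid line. The region with the strongest pro-B excess was at the distal end of chromosome 12, where 114000001 to 117000000 held 2.22 times the ES reads (2.163 to 2.273, 20092 against 9145 reads). Chromosome 8 was lower at 0.778 times (0.775 to 0.780), and the other 18 autosomes lay between 0.952 and 1.08 times. Relative to the median autosome of its own library, chromosome 8 had a read density of 0.884 in pro-B cells, 1.147 in untreated ES cells, 1.241 in SB431542-treated ES cells and 1.125 in myotubes. Chromosome X was at 1.16 times (1.158 to 1.168), chromosome Y at 0.709 times (0.683 to 0.736) and mitochondrial reads at 0.454 times (0.360 to 0.569, 113 against 250 distinct positions), or 0.252 times with the SB431542 library as the reference.

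In 1 Mb bins, 105 were higher and 110 lower in pro-B cells, and scaling to the median autosomal bin made these 159 and 74, so that 68.2% in place of 48.8% of the called bins were higher. The 6 higher regions were, besides that on chromosome 12, on chromosome X from 103000001 to 108000000 (1.62 times), chromosome 1 from 143000001 to 149000000 (1.55 times), chromosome 14 from 92000001 to 95000000 (1.53 times), chromosome 10 from 48000001 to 51000000 (1.46 times) and chromosome 14 from 108000001 to 111000000 (1.43 times). Of the 6 lower regions 5 lay on chromosome 8, from 0.631 times (44000001 to 47000000) to 0.670 times (28000001 to 35000000), and the sixth was chromosome 5 from 131000001 to 134000000 at 0.676 times (0.660 to 0.692). Over all chromosome 8 bins the median log2 ratio was -0.39, with an SD of 0.24. Its 5 regions thus passed the rule on a chromosome that was lower as a whole, and they are not read as local features. Pro-B and ES cells correlated with r = 0.666 across 100 kb bins, with a spread of the log2 ratio 4.24 times that of counting and 195 bins at least 2-fold apart. These values include chromosome 8 with its lower level. With a rule of size of 0.3 in place of 0.5, 394 bins were higher and 404 lower.

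**Figure D3:**
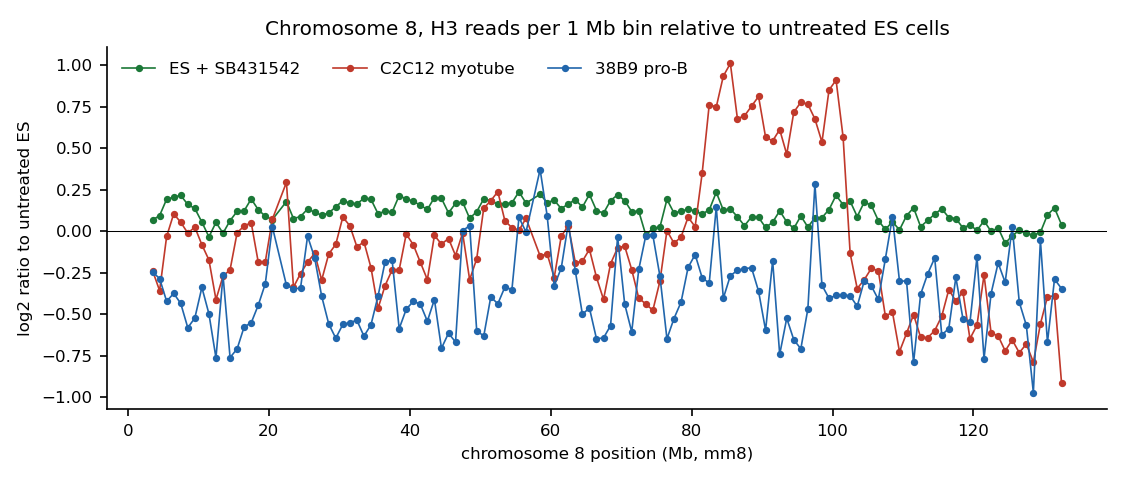
Log2 ratio of H3 reads to untreated ES cells along chromosome 8 in 1 Mb bins, with 1 line per library. The myotube line steps up from 82000001 to 102000000 to log2 ratios of 0.46 to 1.01 and lies below 0 from 107000001 to 131000000, the SB431542 line lies above 0 in 119 of 128 bins, and the pro-B line lies mostly below 0.

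Myotubes and pro-B cells were also set against each other. Myotubes were higher on chromosome X (1.71 times, 1.707 to 1.721), chromosome 8 (1.27 times, 1.268 to 1.277) and chromosome 15 (1.26 times, 1.252 to 1.260), and lower on chromosome 7 (0.790 times, 0.787 to 0.793). The region at the distal end of chromosome 12 from 114000001 to 117000000 was at 0.407 times in myotubes (0.396 to 0.418). On chromosome 8 myotubes were at 2.09 times from 81000001 to 97000000 and at 2.13 times from 98000001 to 102000000. On chromosome X the named regions ranged from 1.75 times (126000001 to 143000000) to 2.25 times (20000001 to 24000000). On chromosome 7 the lower regions were 97000001 to 103000000 at 0.609 times, 119000001 to 123000000 at 0.633 times and 43000001 to 46000000 at 0.654 times. The regions on chromosomes X and 7 again lay on chromosomes shifted as a whole. In all, 264 bins were higher and 126 lower, and scaling to the median bin gave 214 and 173, or 55.3% higher in place of 67.7%. A rule of size of 0.3 gave 638 and 413. Without chromosome X the counts were 127 and 124. These libraries had an r of 0.623 across 100 kb bins, with 378 bins at least 2-fold apart. Both values include the shifted chromosomes 7, 8 and 15.

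At finer scale, and chosen after the data had been seen, stretches without any read were counted in each library. The longest in myotubes lay on chromosome 4 from 88735728 to 88950666 (215 kb), and a single read parted it from a further stretch that ended at 88978835. Joined across that read they spanned 243 kb, with 1 read against 1028 in untreated ES, 1085 in SB431542-treated ES and 1358 in pro-B cells, a ratio to untreated ES of 0.00103 (2.60e-05 to 0.00574). In pro-B cells the longest lay on chromosome 12 from 113877448 to 114022505 (145 kb), reaching into the start of the region with the highest ratio, with 0 reads against 290, 311 and 261 in the untreated ES, SB431542 and myotube libraries. The interval of the ratio to untreated ES cells reached up to 0.0129, and in reads with 2 places pro-B cells had 24 lines there against 322. By the rule of more than 10 kb without a read, myotubes had 28 such stretches (1.04 Mb in all) and pro-B cells 20 (0.604 Mb in all), and with at least 20 kb required, the counts were 17 and 10. A stretch absent from the ES line itself would be empty in both ES libraries and so could not be counted by this rule. With the SB431542 library left out, the counts were 30 for myotubes, 21 for pro-B cells and 0 for untreated ES cells. Strain differences from the reference genome may empty stretches more readily in some lines than in others, which was not tested. The counts are therefore not read as numbers of deletions.

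**Figure D4:**
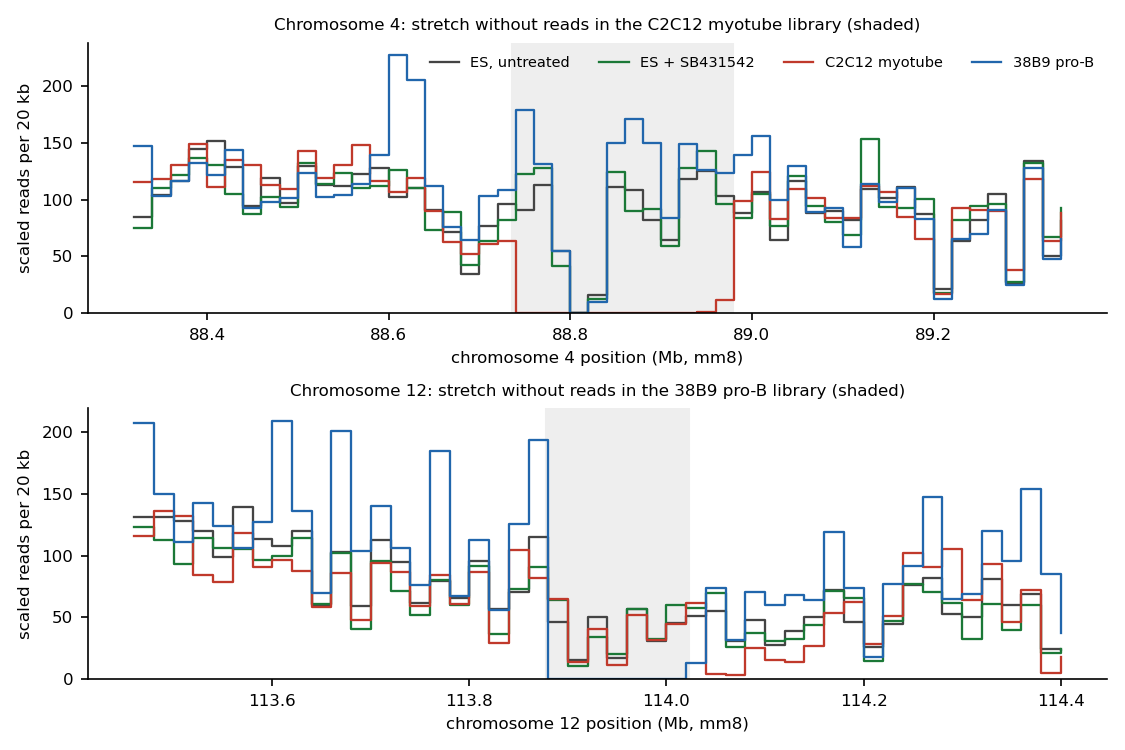
Scaled H3 reads per 20 kb in the 4 libraries around the longest stretches without reads on chromosomes 4 and 12, with 1 line per library and the stretch shaded. On chromosome 4 the myotube line lies at or near the axis across the shaded 243 kb, and on chromosome 12 the pro-B line does so across 145 kb. Bins at the edges reach past the stretches and take in reads from outside them, 11 in myotubes and 13 in pro-B cells in the last bin of each. The other libraries hold reads over most of both stretches, with 1 bin of the chromosome 4 stretch at 0 in all 4.

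Pro-B cells also carried many narrow sites with more reads. Of 2628002 windows of 1 kb, 4236 were higher in the pro-B library than in every other library by the rule for windows, where counting alone gave 9. The same rule gave 126 windows for myotubes, with 6 from counting alone. It gave 39 for SB431542-treated and 26 for untreated ES cells, with 16 and 10 from counting alone, but each ES library was there set against a library of its own line, which holds its count down. With the SB431542 library left out, the counts were 6371 for pro-B cells, 279 for myotubes and 99 for untreated ES cells, with 46, 24 and 40 from counting alone. With the untreated ES library left out, SB431542-treated cells had 216, with 54 from counting alone. In pairs, 10057 windows were higher in pro-B than in untreated ES cells and 260 the other way, and 538 were higher in myotubes than in untreated ES cells and 354 the other way. Counting alone gave 314 and 310 for the first pair and 234 and 320 for the second. Between the ES libraries 310 windows were higher with SB431542 and 116 without, where counting alone gave 302 and 251. The counting values were drawn around the mean of the observed counts, which themselves hold counting noise, so they may lie too high. Observed counts near or below them, as 116 against 251 and 260 against 310, are therefore not read as a lack of difference. At 2 times in place of 3 times the highest other library, the pro-B count was 12691, and with all reads as deposited the myotube count was 200, the SB431542 count 106 and the untreated ES count 41. The densest 1 Mb bins for pro-B windows were chromosome 12 from 116000001 (52 windows) and from 115000001 (40 windows) and chromosome 11 from 44000001 (36 windows). In positions held out from the choice of 7156 windows, pro-B reads were 17.5 per kb at the window, 9.65 per kb at 5 to 10 kb and 8.86 per kb at 15 to 20 kb. Untreated ES reads were 6.85, 5.96 and 5.91 per kb at the same places. The held-out ratio of pro-B to the highest other library was 2.55 at the window (2.51 to 2.59 over resampled windows) and 1.62 at 5 to 10 kb.

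**Figure D5:**
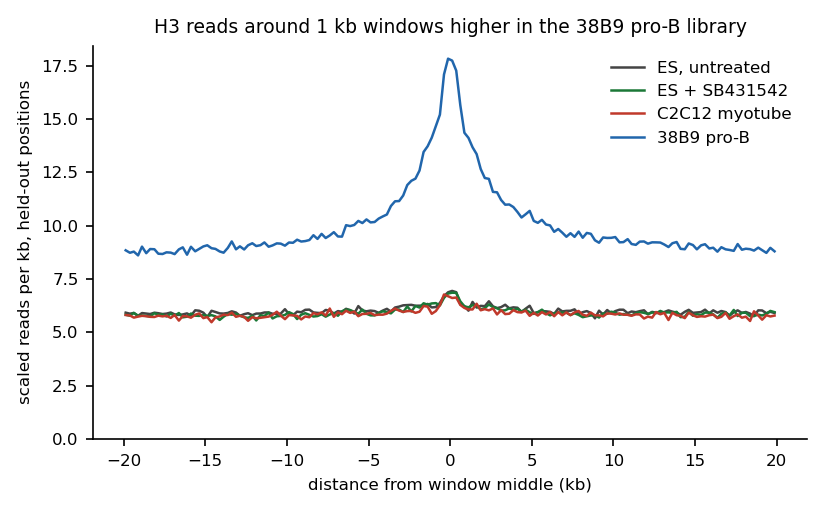
Mean scaled H3 reads per kb, in held-out positions, against the distance in kb from the middle of 7156 windows of 1 kb chosen as higher in pro-B cells, with 1 line per library. The pro-B line averages 17.5 per kb over the central 1 kb and 8.86 per kb at 15 to 20 kb, and the untreated ES line averages 6.85 and 5.91 per kb there.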

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

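Reads with 2 reported places stayed outside the main values of the comparisons above, and they were more frequent at some places in pro-B than in untreated ES cells. In 1 Mb bins of this section, 5 of 2331 autosomal bins were at least 2-fold higher in pro-B than in untreated ES cells. They lay on chromosome 12 from 114000001, 115000001 and 116000001, with log2 ratios of 1.201, 1.503 and 1.836, and on chromosome 6 from 68000001 and 69000001, with log2 ratios of 1.06 and 1.09. In the mouse the heavy chain immunoglobulin genes lie at the distal end of chromosome 12 and the kappa light chain genes on chromosome 6, and no gene was placed on these bins. The SB431542 library had no bin 2-fold higher or lower, and the myotube library none higher. At least 2-fold lower than untreated ES were 5 bins in myotubes and 5 in pro-B cells. In reads with 1 place all 5 higher bins were also above the ES level, at 2.12, 2.90 and 1.96 times on chromosome 12 and at 1.88 and 1.89 times on chromosome 6.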

How the results depend on the processing

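The first 5 alternatives named below were set before the data were examined, and those with 2-place reads, the other reference, no chromosome X, and windows and stretches were chosen after. Of 171 chromosome, bin, window and stretch values under alternatives, 105 stayed within counting error or, for counts, within 1.5-fold, and 66 moved. No chromosome or region ratio crossed 1 in 199 recomputed ratios. The balance of higher and lower bins did turn, from 48.8% to 68.2% higher in pro-B cells with the other scaling and from 74.4% to 38.0% higher in myotubes without chromosome X. The cause was not tested unless the alternative itself sets it, as a looser limit does for counts. The ratios of the named regions and of the parts of chromosome 8 kept their direction, at 0.844 to 1.09 times the reported value with 2-place reads, 0.972 to 1.04 times with all reads and 0.961 to 1.04 times with the other scaling. No paired analysis was possible because each group had 1 library. The promoter, gene body, gene list and GC alternatives were not run. Counting error was small beside most differences, but not on chromosome M or in 1 kb windows, where depth limits what could be called.

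With all reads as deposited, chromosome M was at 2.15 times in the SB431542 library, chromosome Y at 0.0109 times in myotubes and 0.640 times in pro-B cells. The 100 kb spread was then 4.37 times counting for pro-B against ES and 4.55 times for myotube against pro-B, and the 1 kb windows numbered 41 (untreated ES), 106 (SB431542) and 200 (myotube).

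Scaling to the median 1 Mb bin gave 1.09 times (chromosome 8) and 1.04 times (X) for SB431542 and 0.807 times (8) and 1.21 times (X) for pro-B, with 159 bins higher in pro-B. For myotube against pro-B it gave 0.759 times (7), 1.22 times (8), 1.21 times (15) and 1.65 times (X).

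Without a minimum count, 3 bins were higher and 4 lower in SB431542-treated than in untreated ES cells. A rule of size of 0.3 gave 1 lower bin for SB431542, 251 higher and 180 lower bins for myotube against ES, 394 higher and 404 lower for pro-B, and 638 higher and 413 lower for myotube against pro-B. Thinning to the shallowest library gave a 100 kb spread of 4.18 for pro-B against ES and 16 windows for untreated ES.

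With 2-place reads, chromosome M was at 1.53 times in SB431542-treated cells. Myotubes were at 0.759 times (7), 1.94 times (X) and 0.0460 times (Y), pro-B cells at 0.782 times (8) and 1.15 times (X), and myotube against pro-B at 0.801 times (7), 1.27 times (8) and 1.69 times (X). The 100 kb r fell to 0.926 for SB431542, 0.678 for myotube, 0.617 for pro-B and 0.580 for myotube against pro-B, and the spread was 4.35 for pro-B and 4.49 for myotube against pro-B.

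Against SB431542-treated ES cells as the reference, myotubes were at 0.771 times (7), 0.916 times (8) and 1.93 times (X), and pro-B cells at 0.720 times (8), 1.13 times (X) and 0.252 times (M). The r was 0.776 for myotubes and 0.651 for pro-B cells, with a spread of 4.35 for pro-B cells. Without chromosome X, 38 bins were higher in myotubes than in ES cells and 127 higher than in pro-B cells.

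At 2 times the highest other library the windows numbered 173 (untreated ES), 434 (SB431542), 703 (myotube) and 12691 (pro-B). Stretches of 20 kb or longer numbered 17 in myotubes and 10 in pro-B cells, and those with 50 or more reads in each other library 18 and 11. Without the SB431542 library the windows numbered 99 (untreated ES), 279 (myotube) and 6371 (pro-B), and without the untreated ES library 216 (SB431542) and 270 (myotube).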

Other observations

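The test of the read density trend on myotube reads was chosen before its result was seen, and all other tests in this part after. Single 1 Mb bins added features that the regions did not cover. In pro-B cells chromosome 11 from 44000001 to 45000000 was at 2.07 times the ES level (2.005 to 2.132), with the myotube library at 1.06 times. Chromosome 16 from 81000001 to 82000000 was at 1.91 times (1.848 to 1.975) in pro-B and at 1.18 times in myotubes. In both myotubes and pro-B cells chromosome 4 was lower from 112000001 (0.449 and 0.484 times), from 121000001 (0.558 and 0.506 times) and from 145000001 (0.572 and 0.508 times), while the SB431542 library had 1.02, 0.996 and 1.00 times there. A strain difference between the ES line and the other lines was not tested for these bins. Chromosome X from 120000001 to 121000000 was at 0.128 times the untreated ES level in myotubes (155 against 1276 reads), against about 2-fold higher reads over most of that chromosome. Pro-B cells were also lower in this bin, at 0.648 times (0.593 to 0.708, 819 against 1276 reads). In reads with 2 places, chromosome 4 from 121000001 to 122000000 had log2 ratios to untreated ES of -2.24 in myotubes and -2.42 in pro-B cells.

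For the higher share of chromosome 8 in the SB431542 library, a trend on myotube read density and chromosome position was fitted on 16 other autosomes. Removing it left the median log2 ratio of chromosome 8 at 0.12, where the medians of the other autosomes ran from -0.03 to 0.02. This argues against a coverage bias that follows the trend as the whole cause. The trend explained only 0.11 of the variance of the log2 ratio. Other coverage biases stay open, and GC content was not tested. Myotubes themselves differ along chromosome 8, and pro-B density in the same trend also left a median of 0.12. A few regions alone are argued against by the 93.0% of its bins above 0, and an even copy gain in part of the treated culture may account for it but is not established, as the log2 excess was 0.14 in the proximal and 0.05 in the distal part after the myotube trend. Bins past 80% of its length minus those up to 60% gave -0.069, or -0.107 without a trend, within the ranges of the 16 other autosomes (-0.12 to 0.09 and -0.17 to 0.05), and treatment, culture and sequencing run stay open. The untreated library it is set against had itself 1.147 times the density of its median autosome on chromosome 8, and whether either ES culture carries a gain is not settled here.

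The chromosome 4 stretch held 1 read in myotubes, and a chance gap is argued against by the 1091 reads that the other libraries predict there. The rule for stretches itself required at least 30 reads in every other library. With reads reassigned at random among the libraries, myotubes had 0 such stretches in place of 28. A move of its reads to the section with 2 places is argued against by the 17 lines of that section over the stretch, 0.541 times the scaled mean of the other libraries and far fewer than the reads missing. A deletion in the C2C12 line may account for it, and so may a strain difference from the reference, which was not tested. Loss of H3 without loss of DNA cannot be told apart from a deletion, because 0 input libraries were used here.

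For the held-out profile, 7156 windows of 1 kb with more reads in pro-B cells had been chosen on a part of the positions. Reads shared with a second place are argued against for most of these windows. Of them, 76.2% had no 2-place line in any library, and in this part the held-out ratio to the highest other library was 2.55 (2.496 to 2.579). Copy gain of the surrounding region is argued against as the whole cause by the ratio at the window over that at 5 to 10 kb. This quotient was 1.58 (1.547 to 1.603 over resampled windows). Among the 4236 pro-B windows called on all positions, 33.5% had the next window within 10 kb. Windows were resampled as if independent, so the intervals over resampled windows may be too narrow. Pro-B reads were still 1.62 times the highest other library at 5 to 10 kb, so a wider difference, copy number included, may account for part. Neighbouring windows may also lie in that flank and raise its ratio. Chromosomes 8 and X held 1.42% and 0.307% of the 4236 pro-B windows called on all positions, and the calls were not corrected for copy number. Sites of a pro-B chromatin state that yields more H3 may account for the windows, a hypothesis that was not tested. An antibody or recovery effect of this library cannot be told apart from it, because 0 further pro-B libraries were used here. A pro-B library from another preparation with another H3 antibody would bear on such an effect. It would not bear on a recovery effect shared by pro-B preparations, and no input library was used here.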
